A study of Mus musculus with 2 samples.

How the data were processed

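Whole bone marrow of a KrasG12D/+ mouse and of a wild-type mouse was embedded in OCT and frozen, per the labels' protocols. Sections of 10 µm were cut, laid on BMKMANU S1000 capture slides, fixed, stained with haematoxylin and eosin and imaged, and libraries were sequenced on an Illumina NovaSeq instrument with paired reads, per the labels' protocols. The label of the wild-type library names the slide type S1001 in place of S1000. Both libraries carry the batch label 1. The labels give 1 section per genotype, so the animal, the section, the slide and the genotype cannot be told apart.

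The deposited files are a sparse table per section of whole-number counts for each gene and barcode, with no normalization. The build was mm10, per the submitters' processing notes, while the aligner, the counting tool and the annotation are not given in the sources used here. Whether a count is a molecule marked by a unique identifier or a read is likewise not given. Intervals and floors cover counting error only, and that only if each count is a separate molecule. Strand handling is not given, so overlapping and antisense genes may share counts. The series' design text speaks of spots under tissue, but a table of positions or of tissue cover was not used here, and the 2 lists of barcodes were identical. Spots with at least 250 counts were therefore kept in place of spots over tissue, and no map of the sections was drawn. No doublet caller was run, since a spot can hold several cells.

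Counts of the kept spots were summed per gene and divided by the section total (35993750 in the KrasG12D/+ section and 12897820 in the wild-type section) to give CPM. Genes with at least 20 counts over both sections were called measured. Levels have exact Poisson intervals and log2 ratios have Clopper-Pearson intervals conditional on the sum, all at 95%. A count of 0 was set to 3 counts for a ratio, which is 0.0833 CPM in the KrasG12D/+ section and 0.233 CPM in the wild-type section, and such ratios are bounds. No gene was tested, because 1 library per group gives no estimate of the spread between animals. A size rule took the place of a test, at least 2 times higher or lower with a mean of at least 10 CPM.

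The 38 gene lists (23 of cell types, the others of pathways and technical classes) were fixed before the data were examined, as were the rule for named genes and all alternatives except those marked as later choices. Of each list the median log2 ratio of its measured members was taken, with its percentile among 10000 random lists of the same size drawn from 20 bins of mean CPM, as a description of these libraries. Where a symbol had several identifiers, the one with the most counts was used. Through a synonym in the table of RefSeq genes of GRCm38, H2az1 was read as H2afz, and of the 54838 identifiers 37814 (69.0%) had a symbol in that table, from which coordinates in the same build were taken. The named genes were Kras, the 15 highest and 15 lowest ratios among genes with a mean of at least 50 CPM (without unnamed gene models), the 4 measured members of each list with the highest mean CPM, and the 5 genes of each region with the highest fold over the rest of its section at 50 CPM or more. Gata1, Klf1, Cd19, Rag1, Csf3r and Xist, and in the closing section Cxcr2, Mmp8, Mxd1, Epx, Fcer1a, Ctsk, Ibsp, Runx2 and Cstb, were chosen after their values were seen.

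To compare shares of spots, each kept spot was thinned without replacement to 250 counts, and the share of spots with at least 1 count was given with its exact binomial interval. Cell type lists with at least 0.2 counts per thinned spot in both sections were compared by Spearman correlation over spots, without the genes a pair shares, and beside it stands the value for spots drawn from the section's mean profile. Regions were found in each section apart, from 2000 variable genes, 20 principal components and 15 neighbours, by Leiden clustering at resolution 0.5.

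The alternatives were other choices of spots (all barcodes, at least 1000 counts, or above the Otsu threshold of 314 and 145 counts), of scaling (edgeR's TMM factors, DESeq2's median-of-ratios factors, totals without haemoglobin or without mitochondrial and ribosomal protein genes), of weighting, thinning, count minimum, resolution and components. Added after seeing the data were a total without haemoglobin, S100a8 and S100a9, and the spots outside regions where the osteoblast, osteoclast or skeletal muscle list had at least 3 times its share elsewhere (30998 and 18217 spots). On simulated data for KrasG12D/+ against wild-type, 92.0% of 100 genes set 4 times apart passed the size rule, as did 0 of 9728 unchanged genes, and 95.2% of 18916 intervals held the true ratio. The simulation drew Poisson counts from a shared mean profile, without spread between animals or a broad shift in composition. It therefore checks counting error only, and not how many genes pass the rule without cause in these sections. Tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.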

Results

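Spatially barcoded RNA was measured in bone marrow of 2 mice, 1 with the KrasG12D/+ genotype (an activating point mutation in 1 allele of the RAS gene Kras) and 1 wild-type. A frozen section of 10 µm from each mouse was laid on a slide of barcoded spots, where a spot is a small region that can hold several cells. The deposited tables of counts held 64240 barcodes and 54838 features per section, with 39179096 counts in the KrasG12D/+ section and 16674073 in the wild-type section. Spots with at least 250 counts were kept, which left 36882 spots (57.4%) with a median of 876 counts in the KrasG12D/+ section and 20164 spots (31.4%) with a median of 552 in the wild-type section. The genotypes had 1 section each, so no difference below was tested or checked in a replicate, and every value describes these 2 libraries. Intervals in parentheses are exact 95% intervals of the counts and cover counting error only, provided that each count is a separate molecule. Levels are CPM, a gene's counts over the kept spots scaled to the total of its section, and ratios are KrasG12D/+ over wild-type on the log2 scale.

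**Figure D1:**
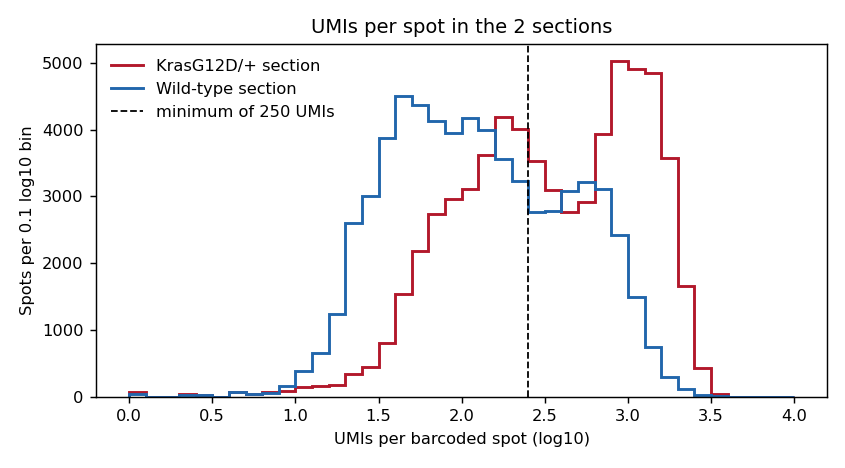
Number of spots (vertical axis) against counts per spot (horizontal axis, log10) in each section, with a dashed line at the minimum of 250 counts. The kept spots had a median of 876 counts in the KrasG12D/+ section and 552 in the wild-type section.

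Kras itself (ENSMUSG00000030265, chromosome 6, 145216699 to 145250420 in mm10) had 34.4 CPM (32.5 to 36.4) in the KrasG12D/+ section and 52.8 CPM (48.9 to 56.9) in the wild-type section, a log2 ratio of -0.62 (-0.75 to -0.48). The genotype label names an amino acid substitution and not how the allele was built, so the level of the gene does not check the labels. The ratio depended on the alternative chosen, from -0.90 to -0.14, and the median of genes with a mean of at least 10 CPM was -0.35. The cause of the lower level was not tested.

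The comparison of the sections asks which genes differ in level between marrow with and without the mutant allele. Genes of granulocytes and monocytes took a larger share of the KrasG12D/+ library, and genes of red cell precursors, platelets and B cells took a larger share of the wild-type library. S100a8 and S100a9, which encode the calcium-binding proteins of neutrophils, made up 16.4% of the counts in the KrasG12D/+ section and 3.74% in the wild-type section. The haemoglobin genes made up 1.54% and 19.0%. Of 18598 measured genes, 9952 had a mean of at least 10 CPM. Among them 678 were at least 2 times higher and 2265 at least 2 times lower in the KrasG12D/+ section, and 55 and 199 were at least 8 times higher and lower. The median log2 ratio of these genes was -0.35. The split depended on the scaling, with 1543 higher and 1121 lower under TMM factors, 1603 and 1090 under median-of-ratios factors, and 421 and 3569 when haemoglobin was left out of the total. Those scalings moved the median of all genes by 0.47, 0.50 and -0.30, so each list below has its median log2 ratio followed by the difference from the median of all genes. That median also depended on level, with -0.05 at a mean of at least 50 CPM and -0.48 at a mean of at least 1 CPM. The percentile beside a list allows for this, since its random lists were matched on expression, and their central value ran from -0.65 for the T and NK cell list to 0.36 for ribosomal protein genes.

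**Figure D2:**
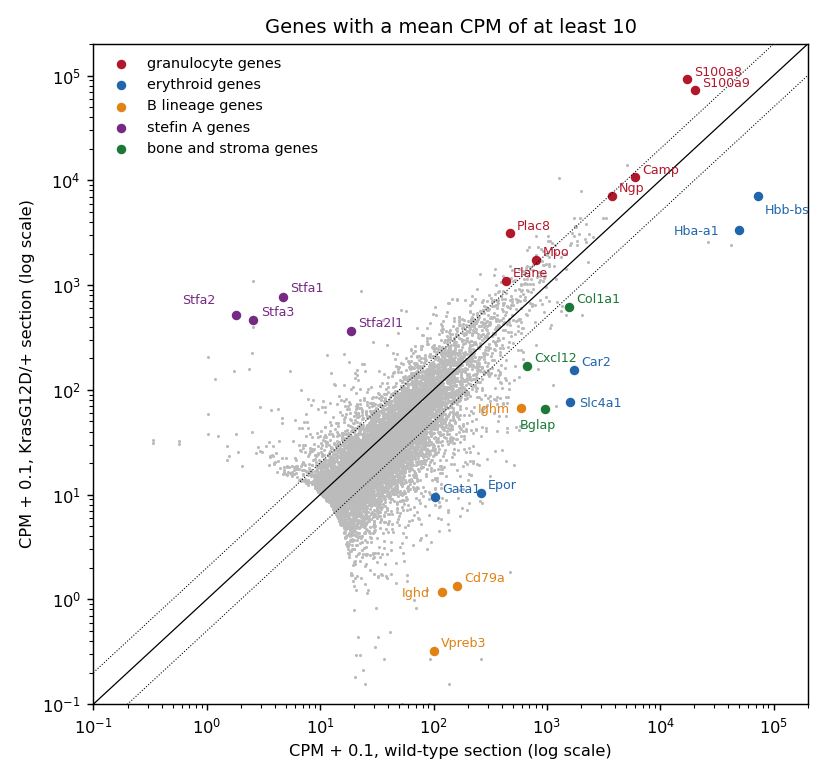
Each point is a gene with a mean of at least 10 CPM, plotted by its CPM plus 0.1 in the wild-type section (horizontal axis, log scale) and in the KrasG12D/+ section (vertical axis, log scale), with a solid line at equal levels and dotted lines at a difference of 2 times. Among the coloured points, which are named genes, the stefin A genes, S100a8, S100a9, Camp, Ngp, Elane, Mpo and Plac8 lie above the solid line, and the erythroid genes, Cd79a, Vpreb3, Ighd, Ighm, Bglap, Col1a1 and Cxcl12 lie below it.

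Erythroid genes were lower in the KrasG12D/+ section at every stage measured. The early erythroid list had a median of -3.46 (-3.12 against all genes), and 12 of 12 measured members were at least 1.5 times lower. The transferrin receptor gene Tfrc had 522 CPM in the KrasG12D/+ section and 1486 CPM in the wild-type section, and Car2, a carbonic anhydrase gene, had 155 and 1734 CPM. Epor, the receptor for erythropoietin, had 10.3 CPM (9.31 to 11.4) against 262 CPM (253 to 271), which is 25.4 times lower. The erythroid transcription factor genes Gata1 and Klf1 had ratios of -3.44 and -3.49. The late erythroid list had a median of -3.74 (-3.39 against all genes), again with 12 of 12 members lower. Hbb-bs, a beta-globin gene, had 7059 CPM (7031 to 7086) and 72387 CPM (72240 to 72534), a ratio of -3.36. Hba-a1 and Hba-a2, the alpha-globin genes, had ratios of -3.86 and -4.13. Both erythroid medians lay below all 10000 expression-matched random lists of the same size, at the 0.0 percentile.

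Megakaryocyte and platelet genes were also lower, with a median of -2.34 (-2.00 against all genes, 0.0 percentile) and 12 of 12 members at least 1.5 times lower. Pf4, the gene of platelet factor 4, had 388 CPM in the KrasG12D/+ section and 1068 CPM in the wild-type section, and Ppbp, a platelet chemokine gene, had 133 and 567 CPM. Itga2b and Gp9, which encode parts of platelet surface receptors, had ratios of -2.09 and -2.03.

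B lineage genes had the lowest median of the cell type lists, -5.29 (-4.94 against all genes, 0.0 percentile), with 13 of 14 members at least 1.5 times lower and a median of -4.26 over members with a mean of at least 10 CPM. Cd79a, a signalling chain of the B cell receptor, had 1.25 CPM (0.912 to 1.67) in the KrasG12D/+ section and 162 CPM (155 to 169) in the wild-type section, and Cd19 had 6 and 1189 counts. No count of Rag1, which recombines antigen receptor genes, was found in the KrasG12D/+ section against 226 in the wild-type section, at least 210 times lower when the absent side is set at 3 counts. Ighm, the IgM heavy chain gene, had 67.5 and 587 CPM, and Cd74, the class II invariant chain, had 130 and 368 CPM. The kappa light chain gene Igkc was the exception at 346 CPM (340 to 352) and 348 CPM (338 to 358). Plasma cell genes did not move together, with a median of -0.22 (0.13 against all genes, 59.5 percentile) that became positive under TMM and median-of-ratios factors and outside the regions rich in bone or muscle genes. Ighg2c, an IgG heavy chain gene, was higher in the KrasG12D/+ section at 184 against 17.9 CPM, a ratio of 3.36 that was 4.67 over spots with at least 1000 counts. Igha, the IgA heavy chain gene, had 337 and 518 CPM, Ighg2b had 91.9 and 97.2 CPM (a ratio of -0.08 that was -0.76 over spots with at least 1000 counts and 1.07 outside the regions rich in bone or muscle genes), and Xbp1 had 103 and 84.4 CPM. T and NK cell genes had a median of -2.08 (-1.74 against all genes, 0.0 percentile), with 10 of 14 members lower and 1 higher. The low median rested on members with few counts, as the 4 members with a mean of at least 10 CPM had a median of -0.39, close to that of all genes, and members measured from 100 counts had -1.16. Il7r, the interleukin-7 receptor, had 0.722 and 30.7 CPM, a ratio of -5.41 that was -8.17 over thinned spots, where 1 KrasG12D/+ spot held a count. By contrast the granzyme gene Gzma had 19.7 and 9.69 CPM and Ccl5 had 16.8 and 21.2 CPM, a ratio of -0.34 that became positive under TMM and median-of-ratios factors. The dendritic cell list had a median of -1.02 (-0.68 against all genes, 3.18 percentile) and the list of class II antigen presentation -1.04 (-0.69 against all genes, 1.75 percentile). H2-Ab1 and H2-Aa, class II genes of both lists, had ratios of -1.23 and -0.95, while the protease gene Ctss of the second list had 2.30.

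Genes of early and immature granulocytes were higher in the KrasG12D/+ section, whereas mature neutrophil genes went both ways. The early granulocyte list, which holds primary granule genes, had a median of 1.43 (1.77 against all genes, above all 10000 random lists), with 10 of 12 members at least 1.5 times higher and none as much lower. Elane, the neutrophil elastase gene, had 1098 CPM (1087 to 1109) and 435 CPM (424 to 447), the myeloperoxidase gene Mpo had 1737 and 800 CPM, and Prtn3 had 1228 and 411 CPM. Plac8 had the highest ratio of the list, 2.73. The immature neutrophil list had a median of 0.89 (1.23 against all genes, 98.1 percentile, where the matched random lists centred on 0.29), with 10 of 12 members higher. Camp and Ngp, genes of secondary granule proteins, had ratios of 0.84 and 0.93, and Lcn2, the gene of the iron-binding protein lipocalin-2, had 1.34. The mature neutrophil list had a median of 1.12 (1.47 against all genes, 99.99 percentile), with 8 of 14 at least 1.5 times higher and 2 lower. Its higher members included the stefin A genes Stfa2 and Stfa2l1, at 8.25 and 4.30, which are taken up below. The median and percentile lean on them in part, and no median without them was taken. S100a8 had 91991 CPM (91892 to 92090) and 17067 CPM (16996 to 17138), 5.39 times higher. S100a9, Wfdc21 and Retnlg had ratios of 1.83, 1.87 and 1.68. The 2 lower members were Csf3r, the receptor for granulocyte colony-stimulating factor, at 104 and 347 CPM, and the cytokine gene Il1b at 6.78 and 37.4 CPM.

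Monocyte genes had a median of 0.91 (1.25 against all genes, 99.93 percentile), with 9 of 14 members at least 1.5 times higher and none as much lower. Ly6c2, a surface antigen gene of inflammatory monocytes, had 1179 and 484 CPM, the lysozyme gene Lyz2 had 3151 and 1655 CPM, and S100a4 had 681 and 135 CPM. Psap had 771 and 643 CPM. The macrophage median was -0.33 (0.01 against all genes, 40.3 percentile) and became positive under TMM and median-of-ratios factors. Apoe, the apolipoprotein E gene, had 423 and 219 CPM, Vcam1 had 111 and 194 CPM, Mrc1 had 157 and 198 CPM, and the complement gene C1qa had 97.3 and 104 CPM. The list of basophil, mast cell and eosinophil genes had a median of 0.48 (0.83 against all genes, 99.9 percentile), in which Prg2, the eosinophil major basic protein gene, had 125 and 21.6 CPM and the basophil protease genes Mcpt8 and Prss34 had ratios of -0.31 and -0.66, the former positive under TMM and median-of-ratios factors. Stem and progenitor genes had a median of -0.75 (-0.40 against all genes, 17.5 percentile). Spi1, a myeloid transcription factor gene, had a ratio of 1.05, Gfi1b, which acts in red cell and platelet precursors, had -3.72, Myb had -0.56 and Cd48 had -0.08.

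**Figure D3:**
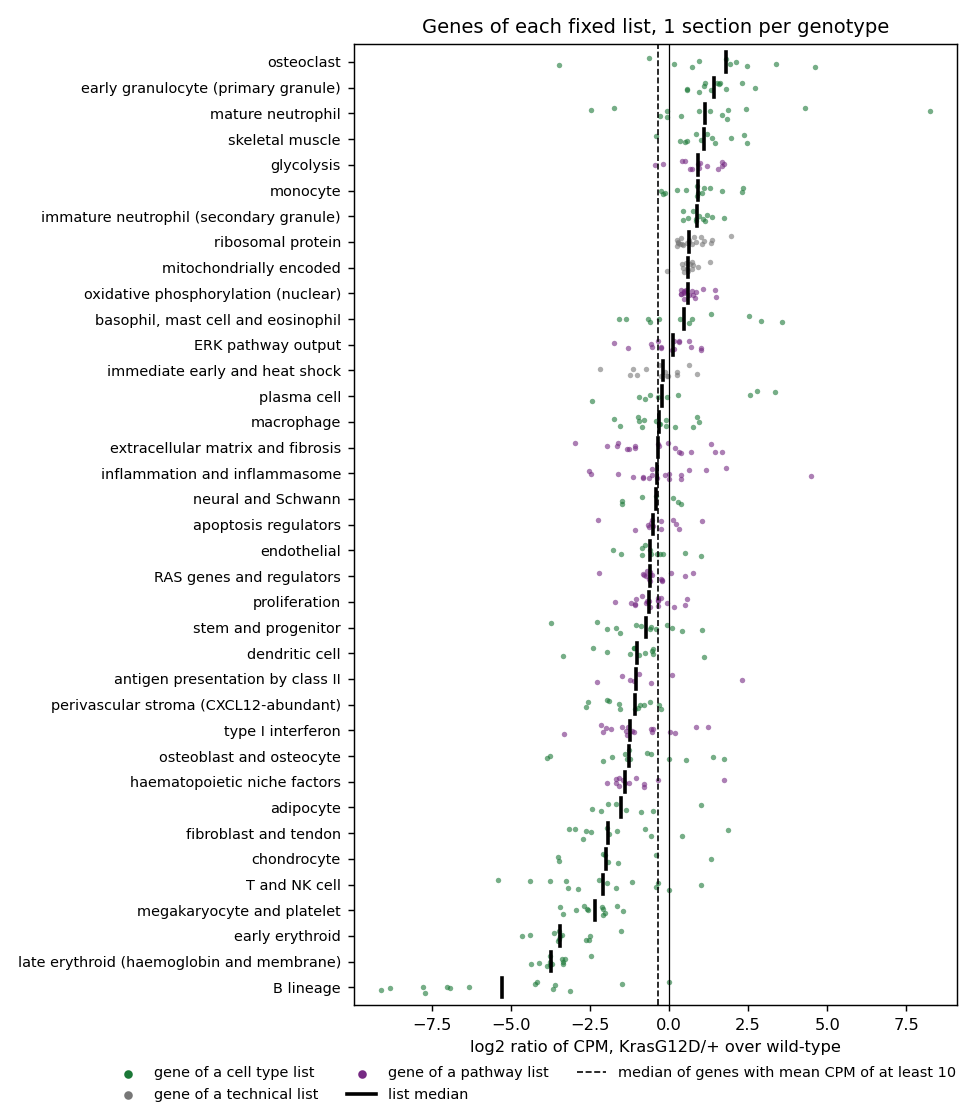
Log2 ratio of CPM, KrasG12D/+ over wild-type (horizontal axis), of each measured gene (points) in each fixed list except the sex chromosome list (rows), with the list medians as black bars and the median of genes with a mean of at least 10 CPM as a dashed line. The medians of the granulocyte, monocyte and glycolysis lists lie to the right of the dashed line, and those of the B lineage, erythroid and megakaryocyte lists lie to its left.

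Genes of bone and stroma were mostly lower in the KrasG12D/+ section, and genes of skeletal muscle and several genes of osteoclasts were higher. Many of these values differed outside the regions rich in bone or muscle genes, an alternative chosen after seeing the data. Those regions were picked by the osteoblast, osteoclast and skeletal muscle lists themselves. Values of genes in those lists can therefore shift by construction, and no cause is read from the shift. The osteoblast and osteocyte list had a median of -1.25 (-0.91 against all genes, 0.14 percentile), with the osteocalcin gene Bglap at 65.5 and 957 CPM and Sparc at 231 and 611 CPM. The collagen genes Col1a1 and Col1a2 had ratios of -1.33 and -1.26, but outside those regions they were 0.069 and 0.041, Sparc was at -0.14, Bglap at -2.98 and the list median at 0.030. The osteoclast list had a median of 1.79 (2.14 against all genes, above all 10000 random lists), but 0.44 over the 6 members with a mean of at least 10 CPM, 0.84 over members measured from 100 counts and 0.96 over spots with at least 1000 counts. Its summed counts made up 0.127% of the KrasG12D/+ library and 0.246% of the wild-type library. Acp5, the tartrate-resistant acid phosphatase gene of osteoclasts, had 85.7 and 51.9 CPM and Mmp9 had 721 and 372 CPM, whereas Tcirg1 had a ratio of -0.63 and Car2, which red cell precursors also express, had -3.49. The skeletal muscle list had a median of 1.10 (1.44 against all genes, 99.98 percentile), with Acta1 at 508 and 130 CPM, Mylpf at 391 and 71.1 CPM, Myh4 at 381 and 190 CPM and Tnnt3 at 306 and 134 CPM. Outside the regions rich in bone or muscle genes its median was 2.41, and Acta1, Myh4 and Tnnt3 had 3.32, 2.60 and 2.36, against 1.97, 1.00 and 1.19 over all kept spots. Perivascular stroma genes had a median of -1.09 (-0.75 against all genes, 1.93 percentile), with 11 of 13 members at least 1.5 times lower. Cxcl12, the chemokine that holds blood stem cells in the marrow, had 170 CPM (165 to 174) and 667 CPM (653 to 681), and Igfbp5 and Kitl had ratios of -1.91 and -0.80. Tnc had -0.27, which became positive under TMM and median-of-ratios factors and outside the regions rich in bone or muscle genes. The niche factor list, which shares Cxcl12, Kitl, Vcam1 and others with those lists, had a median of -1.39 (-1.05 against all genes, 0.2 percentile). Spp1, the osteopontin gene, was the 1 member at least 1.5 times higher, at 290 and 87.2 CPM. Fibroblast and tendon genes had a median of -1.93 (-1.58 against all genes, 0.0 percentile), among them Col3a1 at -2.98, Lum at -2.47, Dcn at -1.89 and Pi16 at -0.76. Chondrocyte genes had -1.98 (-1.64 against all genes, 0.07 percentile), with Col11a1 at -2.08 and Col2a1 at -2.04. Outside the regions rich in bone or muscle genes the fibroblast median was -0.91 (Col3a1 -1.64, Lum -0.91, Dcn -0.91) and the chondrocyte median -0.43 (Col11a1 -0.43, Col2a1 -0.75). Over spots with at least 1000 counts the chondrocyte median was -1.30, and the ratios moved by over 1.5 times were -4.67 for Bglap, -2.17 for Col1a1, -2.07 for Col1a2, -2.09 for Sparc, -2.88 for Col11a1, -2.24 for Col3a1 and 2.84 for Acta1. Adipocyte genes had -1.53 (-1.18 against all genes, 1.0 percentile), or -0.56 over spots with at least 1000 counts, with Adipoq at -1.94, Cfd at -2.43, Scd1 at -2.16 (-3.04 outside those regions) and Lpl at 0.99. Endothelial genes had -0.59 (-0.25 against all genes, 32.4 percentile), with Pecam1 at -0.76, Eng at -0.87, Fabp4 at -0.20 and Ly6c1 at 1.00. The neural and Schwann list had -0.42 (-0.08 against all genes, 65.4 percentile) and the extracellular matrix list -0.34 (0.00 against all genes, 54.7 percentile), and both became positive under TMM and median-of-ratios factors, the neural list also over members with a mean of at least 10 CPM and the matrix list outside the regions rich in bone or muscle genes. In the matrix list Fn1 and Tgfbi had ratios of 1.67 and 1.34.

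Among the pathway lists, glycolysis had the highest median, 0.93 (1.27 against all genes, 99.96 percentile), with 10 of 14 members at least 1.5 times higher. The lactate dehydrogenase gene Ldha had 1511 CPM (1499 to 1524) and 476 CPM (465 to 488), and Aldoa, Pkm and Gpi1 had ratios of 0.94, 0.72 and 0.96. Nuclear genes of oxidative phosphorylation had a median of 0.58 (0.93 against all genes, 85.8 percentile), with Cox6c at 1.48, Cox5a at 1.08, Cox7c at 0.38 and Atp5a1 at 0.36. Mitochondrially encoded genes had 0.60 (0.95 against all genes, 91.2 percentile) and ribosomal protein genes 0.63 (0.97 against all genes, 89.1 percentile). The matched random lists of these 3 lists centred on 0.32, 0.19 and 0.36, and all 3 medians lay within the central 95% of them. In these lists mt-Co1 had 3056 and 1938 CPM, Rpl32 had 7818 and 2011 CPM, and Rps29 had 4378 and 1722 CPM. Proliferation genes had a median of -0.62 (-0.28 against all genes, 0.33 percentile, where the matched random lists centred on 0.19), with 11 of 20 members at least 1.5 times lower and none as much higher. Mki67 had 365 and 555 CPM, whereas Hmgb2 had 1140 and 1206 CPM and Tubb5 had 515 and 365 CPM. Type I interferon genes had a median of -1.25 (-0.90 against all genes, 0.15 percentile), with 11 of 18 members lower and 2 higher. The antiviral gene Rsad2 had 24.8 CPM (23.2 to 26.5) and 247 CPM (238 to 256), and Irf9, Stat1 and Ifi27l2a had ratios of -1.32, -0.53 and 0.85.

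The list of genes induced by ERK signalling, which lies downstream of RAS, had a median of 0.12 (0.47 against all genes, 98.7 percentile), which became negative when haemoglobin was left out of the total. Only 4 of 16 members were at least 1.5 times higher and 2 were lower. Dusp6, a phosphatase gene of the ERK feedback loop, had 69.4 CPM (66.7 to 72.2) and 34.3 CPM (31.2 to 37.7), Spred1 and Spred2 had ratios of 0.70 and 0.31, and Myc had 47.6 and 117 CPM. RAS genes and regulators had a median of -0.60 (-0.25 against all genes, 11.7 percentile), with Rasgrp2 at -0.73, Nf1 at -0.21, Rasa3 at -0.26 and Sos2 at 0.50. The inflammation list had a median of -0.40 (-0.05 against all genes, 67.4 percentile), which became positive under TMM and median-of-ratios factors and over members with a mean of at least 10 CPM. The inflammasome adaptor gene Pycard had a ratio of 1.18, Gsdmd had -0.40, and Nfkbia had 82.4 CPM in both sections. Apoptosis regulators had -0.52 (-0.18 against all genes, 36.3 percentile), with the survival gene Bcl2l1 at -2.26, Mcl1 at -0.54, Mdm2 at -0.65 and Bax at -0.26. Immediate early and heat shock genes had -0.18 (0.16 against all genes, 73.4 percentile), which became positive under TMM and median-of-ratios factors, with Junb at -1.13, Hspa8 at 0.24, Hsp90aa1 at -0.12 and Ier2 at -0.05.

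Among named genes with a mean of at least 50 CPM, the highest ratios belonged to Stfa2, Stfa3 and Stfa1. They are stefin A genes, which encode inhibitors of cysteine proteases. Stfa2 (chromosome 16, 36403946 to 36408363) had 519 CPM (512 to 527) in the KrasG12D/+ section and 1.71 CPM (1.07 to 2.58) in the wild-type section. Stfa3 and Stfa1 had ratios of 7.55 and 7.38, and Stfa2l1, also a stefin A gene, had 4.30. These genes are near copies of one another, so the level of any 1 of them is uncertain. Fgfr3 (chromosome 5, 33721724 to 33737068), a fibroblast growth factor receptor gene, had 224 and 2.40 CPM, and the sugar transporter gene Slc5a10 (chromosome 11, 61672782 to 61720817) had 158 and 2.25 CPM. The clock gene Cry1 had a ratio of 3.77, S100a3 had 3.54 and S100a6 had 3.03. The rest of the 15 were Ighg2c, the mitochondrial tRNA gene mt-Tp at 2.93, and the ribosomal protein pseudogenes Rpl15-ps2, Rps23-ps2, Rpl15-ps3 and Rpl36-ps3, at 3.13 to 4.23, whose counts cannot be separated with certainty from their parent genes. At the low end, Vpreb3, a gene of B cell precursors, had 8 and 1304 counts and a ratio of -8.83 (-10.04 to -7.85). Syt6 (chromosome 3, 103575245 to 103645567) had a ratio of -8.10, Ighd -6.77 and Ly6d -4.66. The red cell antigen gene Kel had -5.03, Dmtn, a gene of the red cell membrane skeleton, had -4.89, and Trim33, Mtif2, Ypel4, Pdzk1ip1, Btnl10, Apol11b and Tspo2 had ratios from -4.94 to -4.59. Over spots with at least 1000 counts Stfa2, Fgfr3 and Vpreb3 had 7.56, 5.93 and -9.63, over thinned spots Stfa2 and Ighd had 9.33 and -8.12, and outside the regions rich in bone or muscle genes Fgfr3 had 7.43. Some ratios close to 0 changed sign with the scaling. Those of Mrc1, C1qa, Igkc, Ighg2b, Cd48, Fabp4, Hsp90aa1, Ier2, Nf1, Rasa3, Hmgb2, Gsdmd and Bax became positive under TMM and median-of-ratios factors, and those of Psap, Hspa8 and Nfkbia became negative when haemoglobin was left out of the total.

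Sex-linked transcripts also differed. Xist, the RNA that silences an X chromosome in females, had 285 counts in the KrasG12D/+ section and 0 in the wild-type section. The Y-linked gene Eif2s3y had 0 and 1164 counts, at least 1083 times lower in the KrasG12D/+ section, Kdm5d had 2 and 318 counts, Uty had 42 and 240, and Ddx3y had 389 and 1076. The list had a median of -3.995 (-3.65 against all genes, 0.0 percentile), which was -8.79 over the 3 members with a mean of at least 10 CPM and -3.35 over thinned spots.

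Shares of spots with a count were taken after each kept spot was thinned to 250 counts. At least 1 count of a B lineage gene was found in 12.3% of spots (11.9 to 12.6) in the KrasG12D/+ section and 33.6% (33.0 to 34.3) in the wild-type section. Igkc, found in 7.52% and 7.28% of spots, gave 12444 of the 20147 B lineage counts in the KrasG12D/+ section and 4486 of 25770 in the wild-type section. Early erythroid genes were found in 20.3% (19.9 to 20.7) and 68.5% (67.9 to 69.2) of spots, and megakaryocyte genes in 13.5% (13.1 to 13.8) and 37.8% (37.1 to 38.4). For early granulocyte genes the shares were 90.4% (90.1 to 90.7) and 47.1% (46.4 to 47.8), and for monocyte genes 81.2% (80.8 to 81.6) and 51.0% (50.3 to 51.7). Some lists had shares that went against their median ratio, so no order is read from them. Osteoclast genes were found in 26.4% (26.0 to 26.9) and 41.2% (40.5 to 41.9) of spots, and their member Car2 alone in 3.66% and 31.4%. Matrix genes were found in 35.1% (34.7 to 35.6) and 28.7% (28.1 to 29.3), and class II presentation genes in 18.5% (18.1 to 18.9) and 17.6% (17.0 to 18.1). Without thinning, B lineage genes were found in 34.7% and 55.6% of spots and early granulocyte genes in 98.9% and 69.3%. Late erythroid genes were found in 92.5% of thinned spots in the KrasG12D/+ section. The profile of spots with under 100 counts resembled that of kept spots, with a Pearson correlation across genes of log2 CPM of 0.955 in the KrasG12D/+ section and 0.966 in the wild-type section, where genes are not independent replicates. In these shallow spots late erythroid genes made up 1.37% and 21.6% of counts, against 1.57% and 19.4% in kept spots.

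Regions were found by clustering the kept spots of each section apart, and their sizes are not compared between the genotypes. The division depended on resolution, number of components and depth. The adjusted Rand index, which is 1 for identical divisions and about 0 for unrelated ones, was 0.444 in the KrasG12D/+ section and 0.920 in the wild-type section at resolution 0.3. With 10 principal components it was 0.352 and 0.496, and after thinning to 250 counts 0.184 and 0.446. The KrasG12D/+ section gave 9 regions, 7 of which held at least 1% of spots. Its largest, region 1 (33.6% of spots, 33.1 to 34.1), was led by Ighg2c, Prss57, Glrx2, Rpl12 and Tomm5, none over 1.91 times its level elsewhere. Region 2 (26.6%), with a median of 454 counts per spot, was led by Gm49124, Catsperd, mt-Tm, Hba-a2 and Gm15601, and region 3 (20.2%) by Slfn4 at 3.22 times, Cdkl4, Clec2d, Eml2 and Neat1. Larger folds were found for bone and muscle genes. In region 5 (4.20%) Bglap2 was 38.5 times and Bglap 34.3 times higher than elsewhere, followed by Col3a1, Col1a1 and Col11a1. Region 6 (3.45%) was led by 6530413G14Rik at 17.4 times and by the osteoclast genes Acp5 at 16.8 times, Ctsk at 11.4 times and Atp6v0d2 at 8.90 times, with Cd109. Muscle genes led region 4 (9.21%; Mybpc2, Gm44646, Actn3, Myom2 and Pgam2) and region 7 (2.29%; Myoz2, Sln, Ppp1r27, Gm44386 and Ankrd2), where Myoz2 was 59.5 times higher. The small region 8 (92 spots) was led by Mirg, Smco1, A530058N18Rik, Mylk4 and Actc1, each on 21 counts or fewer. Region 9 (74 spots) was led by Gm32051, Gm11662, Mpig6b and Pde3a, each on 26 counts or fewer, and by the platelet gene Ppbp at 31.2 times on 406 counts.

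The wild-type section gave 5 regions. Region 1 (50.1% of spots, 49.4 to 50.8) was led by Cmah, Smc5, H2-Q10, Siglecg and Mirt1, none over 2.25 times its level elsewhere. Region 2 (40.3%), with a median of 418 counts per spot, was led by mt-Rnr2, Gm26917, mt-Tq, Gm43841 and Gm10059. In region 3 (5.74%) Bglap was 65.5 times and Bglap2 62.1 times higher than elsewhere, after Cgref1 and Cpz and before Col11a1. Region 4 (2.42%) was led by Lmod3, Gm37759, Dhrs7c, Yipf7 and Ano5, each on 29 counts or fewer, with skeletal muscle genes at 4.71% of counts against 0.0175% elsewhere, and region 5 (303 spots) by Nov, Gm13304, Myoc, Wnt11 and Ccl21a, each on 26 counts or fewer. In region 7 of the KrasG12D/+ section, led by muscle genes, mature neutrophil genes made up 11.0% of counts, against 17.4% elsewhere. In region 4 of the wild-type section late erythroid genes made up 9.93% of counts, against 19.6% elsewhere.

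**Figure D4:**
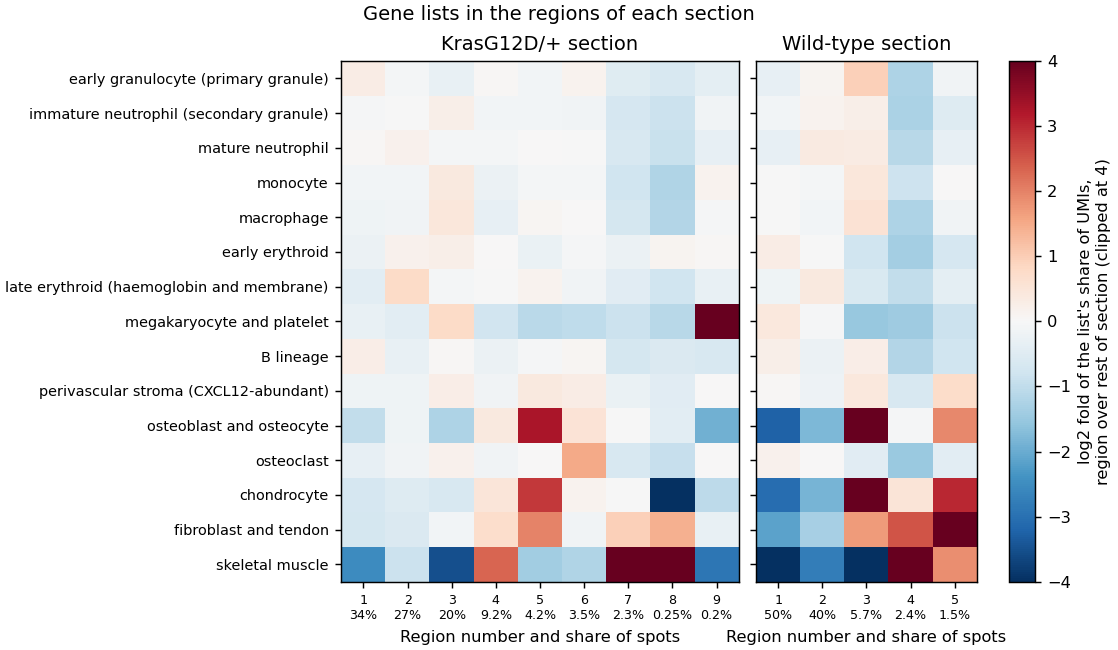
Log2 fold of the share of counts taken by each list (rows) in each region over the rest of its section (columns, with the share of spots under each number), for the KrasG12D/+ section on the left and the wild-type section on the right, clipped at 4 in either direction. The osteoblast list had 32.1 times its share elsewhere in region 3 of the wild-type section and 9.61 times in region 5 of the KrasG12D/+ section.

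Within a section, most pairs of cell type lists had a correlation close to 0 across spots. Of 45 pairs of 10 cell type lists, 40 in the KrasG12D/+ section and 38 in the wild-type section had a Spearman correlation between -0.1 and 0.1 over thinned spots. Immature with mature neutrophil genes had the highest value in the wild-type section, 0.21, and had 0.11 in the KrasG12D/+ section, where spots drawn from a uniform section gave -0.03 and -0.08. Mature neutrophil with late erythroid genes had 0.13 in the wild-type and 0.11 in the KrasG12D/+ section, against -0.10 and -0.06 in uniform spots. Early granulocyte with mature neutrophil genes had 0.09 in the wild-type section and -0.12 in the KrasG12D/+ section, against -0.01 and -0.05, and without thinning the value of the KrasG12D/+ section was 0.73. Late erythroid with skeletal muscle genes had -0.14 in the wild-type section and 0.05 in the KrasG12D/+ section. Spots of 1 section are not replicates, and these differences were not tested.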

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

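Spots with under 100 counts, which are not among the kept spots, carried a signal that stood above the wild-type level. In the KrasG12D/+ section S100a8 and S100a9 made up 15.9% (15.82 to 15.99) of 712288 counts in these spots, against 4.47% (4.43 to 4.50) of 1416795 counts in the wild-type section. The kept spots had 16.4% and 3.74%.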

How the results depend on the processing

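No paired analysis was possible because there was 1 section per genotype and no test. The main interval of a list median was taken from the ordered ratios of its members, and that of a gene, except for bounds, was its counting interval. Of 531 list medians under alternatives, 493 stayed within the main interval and 37 moved beyond it. Only 1, with a main median at least 1.5 times from equal levels, changed sign. Of 2246 log2 ratios of named genes 1285, 959 and 2 did so. List intervals can be wide, as with -0.63 to 3.38 for osteoclast genes, whose median of 1.79 fell to 0.44 within it. Staying within the interval is therefore no measure of stability. Sign changes of smaller values, as in the macrophage, plasma cell, neural, immediate early, ERK, inflammation and matrix lists, are counted in the first 2 groups. The totals without haemoglobin, S100a8 and S100a9 and the spots outside the regions rich in bone or muscle genes were chosen after seeing the data; the others were not. The median of all genes moved by 0.47 under TMM factors, 0.50 under median-of-ratios factors, -0.30 without haemoglobin, 0.10 without mitochondrial and ribosomal protein genes and -0.11 without haemoglobin, S100a8 and S100a9. Genes at least 2 times higher and lower numbered 1543 and 1121 under TMM factors, 1603 and 1090 under median-of-ratios factors, 421 and 3569 without haemoglobin, 367 and 557 at a mean of at least 50 CPM and 1219 and 4749 at a mean of at least 1 CPM, where the number of genes counted differs by construction. List medians under TMM and median-of-ratios factors were 1.88 and 1.91 for early granulocyte, 1.34 and 1.37 for immature neutrophil, -3.28 and -3.26 for late erythroid and -1.89 and -1.86 for megakaryocyte genes, and without haemoglobin -3.74 for early and -4.02 for late erythroid genes, as a single factor moves every ratio alike. Outside the regions rich in bone or muscle genes the osteoblast list had 0.030, Col1a1 0.069 and Col1a2 0.041. Those regions were picked in part by this list, so such a shift can arise by construction, and the cause was not tested. Shares of spots depend on depth by construction: at 500 counts, 100 counts and without thinning, early granulocyte genes were found in 98.5%, 62.9% and 98.9% of KrasG12D/+ and 68.0%, 24.4% and 69.3% of wild-type spots, late erythroid genes in 98.1%, 72.1% and 99.1% of KrasG12D/+ spots, and B lineage genes in 22.7%, 4.95% and 34.7% of KrasG12D/+ and 55.2%, 15.3% and 55.6% of wild-type spots. Without thinning, co-occurrence was 0.70 and 0.33 for early granulocyte with immature neutrophil genes and 0.67 and 0.69 for mature neutrophil with late erythroid genes (KrasG12D/+ and wild-type), and in the KrasG12D/+ section 0.73 for early granulocyte with mature neutrophil genes and 0.23 for mature neutrophil with osteoblast genes; deeper spots hold more of every list. The KrasG12D/+ section had 4 regions with at least 1% of spots at resolution 0.3 and 4 after thinning to 250 counts, against 7, with adjusted Rand indices of 0.444 and 0.184 against the regions described, and the cause was not tested.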

Other observations

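Neutrophil genes differed in their ratios. The list members given here were chosen after their values were seen. While S100a8 and Camp were higher in the KrasG12D/+ section, the surface receptor gene Cxcr2 had 102 and 126 CPM, Mmp8, a collagenase gene of late granules, had 439 and 459 CPM, and Mxd1 had 203 and 211 CPM. Of the 12 measured members of the pooled list of basophil, mast cell and eosinophil genes, 6 were at least 1.5 times higher and 4 as much lower, among them Epx, the eosinophil peroxidase gene, at 11.1 and 0.930 CPM and Fcer1a, a chain of the IgE receptor, at 2.33 and 6.98 CPM. Among osteoclast genes, Ctsk had 106 and 27.8 CPM, while the osteoblast genes Ibsp and Runx2 had 39.2 and 168 CPM and 39.0 and 39.4 CPM. Consecutive barcode numbers fell in the same region for 65.6% of 35200 pairs in the KrasG12D/+ section and 76.9% of 18226 pairs in the wild-type section, where independent labels would give 23.6% and 41.7%.

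Of the tests below, those on neighbours of the stefin genes and on bone and muscle were written before their result was seen, and the others after. Erythroid, megakaryocyte and B lineage genes were lower in the KrasG12D/+ section. The next tests were run on the early erythroid list only. The list lay -3.12 from the median of all genes. This low value is part of the pattern itself and was known when the test was written. It therefore cannot decide whether red blood cells left in the wild-type section are the cause. Haemoglobin, S100a8 and S100a9 taking a large share of the counts are not the whole cause for this list. Without them in the total every ratio moves by the same factor, and the list median was -3.55. Over spots outside the regions rich in bone or muscle genes the early erythroid median was -3.51. The skeletal muscle median there was 2.41, against 1.10 over all kept spots. Leaving those regions out therefore did not make the sections alike in muscle. Whether bone and muscle sampled in different amounts contribute cannot be decided from it. Genotype, sex or another difference between the 2 animals cannot be told apart with 1 section per genotype, and an effect of the mutant allele stays a hypothesis.

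Of the stefin A genes, Stfa1, Stfa2 and Stfa3 were nearly absent from the wild-type section, at 4.57, 1.71 and 2.48 CPM, and Stfa2l1 had 18.6 CPM. The median log2 ratio of Stfa1, Stfa2, Stfa3 and Stfa2l1 was 7.47, against at most 2.73 among the 36 other members of the 3 granulocyte lists. A larger share of neutrophils that raised all their genes alike would not give this gap. The stefin A genes were picked for their high ratios, however, and neutrophil genes differed in their ratios. Whether a larger share of neutrophils in the KrasG12D/+ section is the cause can therefore not be decided from it. Reads shared between paralogs would leave the sum of the family and Cstb level, but its ratio was 5.26. The 15 other genes within 1 Mb had a median of -0.38, with ratios from -3.45 to 0.50. This speaks only against a change that raises the whole interval, since a strain variant need not raise the neighbouring genes. A strain variant of the cluster or of a wider interval may therefore underlie the pattern. It was not separable from a difference in gene activity, as the strains of the animals are not given in the sources used here.

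Xist and Y-linked genes were found mostly in different sections. Animals of different sex are a candidate explanation, and 3 of 4 Y-linked genes were at least 8 times lower in the section with Xist. These counts are part of the pattern itself, so they are no separate test of that explanation. Male cells carried into the KrasG12D/+ section were argued against, because the Ddx3y counts there predict 421 counts of Eif2s3y and 0 were found. Counts of Ddx3y and Uty in that section remain unexplained. If the animals did differ in sex, it would differ together with genotype in these sections.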
